A study of Mus musculus with 10 samples.

How the data were processed

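RNA was measured by sequencing in 10 libraries of mouse melanoma cells of a mixed C57BL/6 and SV129 background. Per the labels, cells were taken from tumours in the skin (primary) or in lymph nodes (metastatic) and sorted by flow cytometry into GFP-positive cells, called c-Myc-high, and GFP-negative cells, called c-Myc-low. The 4 groups held 2 primary c-Myc-high, 2 primary c-Myc-low, 3 metastatic c-Myc-high and 3 metastatic c-Myc-low libraries. Total RNA was amplified before library preparation and sequenced on an Illumina instrument, per the labels' protocols. The kits for extraction, amplification and low-input libraries came from Ambion and Nugen, also per the labels. Sample groups and replicate numbers were taken from the labels. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples.

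The authors deposited 1 table with a row for each of 92214 transcripts under 34162 gene names. Its first kind of column holds estimated counts per transcript, deposited without scaling between libraries. These values need not be whole, and isoforms that cannot be told apart carry equal shares. The second kind holds RPKM, which the authors scaled to transcript length and to a number of reads per library that exceeded the sum of the deposited counts. The submitters' processing notes name Bowtie2, limma and the mm10 build, without versions. The program that assigned reads to transcripts and the annotation release are not given in the sources used here, nor is the strandedness of the counting. Reads of overlapping or near-identical genes were therefore treated as uncertain. All measured columns belonged to a labelled sample, and no row lacked a gene name.

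The total estimated count ranged from 1603012 to 6844328 per library. The row with the highest mean count over all 10 libraries stood for each gene and was rounded to whole numbers. Genes passing edgeR's default expression filter numbered 16272. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, using robust quasi-likelihood tests over all 4 groups with 1 shared estimate of spread and no covariate. The common biological coefficient of variation was 0.984. Benjamini-Hochberg adjustment was applied within each comparison, and genes with an adjusted p under 0.05 were called. The adjusted p-values of single genes in the text are edgeR's unless another tool is named. Standard errors of log2 fold changes were derived from the F statistic.

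Comparisons were metastatic against primary cells within each c-Myc class, c-Myc-high against c-Myc-low cells within each site, the mean of the latter over both sites, and their difference between sites. Fold changes are metastatic over primary, or c-Myc-high over c-Myc-low. Named genes were fixed by rule before the data were examined. They were a panel (Myc, 4 AMPK subunits, Nfe2l2, 4 pigment cell genes and Ptprc), plus up to 10 called genes per direction with the largest change. Those genes needed a mean log2 CPM above 2 and no overlap between the groups. Where no gene was called in a direction, the 5 with the lowest p were taken, and per gene list the 4 members with the lowest p. Predicted genes were counted and not named, and some single genes are not reported here. Beyond this rule, a few abundant members of cell type lists are given, chosen after their values were seen.

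Before the data were examined, 27 pathway lists and 19 lists of cell type markers were fixed, and 42 of these 46 had at least 3 measured members. The mitochondrially encoded genes (0 measured), mast cell and basophil (1), adipocyte (2) and skeletal muscle (2) lists were not tested. Lists were tested with camera and fry in limma 3.58.1, camera with a preset correlation of 0.01 between genes and again with an estimated one. Of the calls by camera, only the keratinocyte list in the 2 site comparisons held with the estimated correlation. A list of salivary gland genes was added after the data had been seen and was used only for levels.

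For a gene with 0 counts in every library of a group, a fold change is given as a bound from a floor of 3 counts over that group. The bound uses the mean of the other group, so it need not hold for each library there. With 1 to 3 counts the ratio is given with an exact 95% binomial interval. Intervals and floors cover counting error only, and the amplified libraries carried no molecular identifiers in the labels. Gene positions are 1-based and come from the GENCODE annotation of GRCm38, the same assembly as mm10, in which 95.7% of the deposited transcripts were found. Positions of Ptprc are not given, because its deposited transcript was not among them.

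Replicates of a group were compared by a chi-square test of counts over genes. The statistic per degree of freedom lay between 40.6 and 238, so no library's counts were a copy of another's in its group. Log CPM values of replicates correlated at 0.509 to 0.579 within the c-Myc-high groups and at 0.749 to 0.886 within the c-Myc-low groups. The shared estimate of spread may therefore be too small for c-Myc-high and too large for c-Myc-low cells. The edgeR procedure was tested on simulated counts with 200 changed genes per comparison, 50 at each of the log2 folds 2, 4, 6 and 10. In the c-Myc-high site comparison it recovered 0%, 0%, 16% and 62% of these, with 2 false calls among 41. For c-Myc status the figures were 0%, 0%, 6% and 36% in primary cells, with 0 false calls among 21, and 0%, 8%, 32% and 58% in metastatic cells, with 4 among 53. DESeq2 recovered more, with 95 false calls among 192 in primary cells and 111 among 219 in metastatic cells. The first simulation held only the 3 lower folds, and the highest was added once little had been recovered.

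Alternatives fixed beforehand were DESeq2 size factors or upper-quartile scaling, no count filter or a filter of 50 counts in 2 libraries, and DESeq2 1.42.0, limma-voom with and without quality weights. Further ones were limma-trend on log2(RPKM + 0.5), transcripts summed per gene, only the groups compared, a replicate block, and each library left out in turn. Fits of the 8 deepest libraries, and fits without the 2 metastatic c-Myc-high libraries rich in salivary gland transcripts, were added after the data had been seen. The former dropped primary c-Myc-high replicate 2 and metastatic c-Myc-high replicate 3, which left only replicate 1 in primary c-Myc-high. The latter left only replicate 2 in metastatic c-Myc-high. The spread of such a group is taken from the other groups.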

Results

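Transcript abundance was measured in melanoma cells sorted from skin tumours and from lymph node metastases of mice, each divided by a GFP sort into c-Myc-high and c-Myc-low cells. The total estimated count was 5075407 and 1603012 in primary c-Myc-high replicates 1 and 2, and 6844328 and 3314654 in primary c-Myc-low replicates 1 and 2. Metastatic c-Myc-high replicates 1, 2 and 3 held 4425636, 4328063 and 2641865 counts, and metastatic c-Myc-low replicates 1, 2 and 3 held 6009730, 5855639 and 4740015. A count of 3 in 1 library stood for 0.471 to 3.57 CPM. The 3 most abundant transcripts took between 4.53% and 21.6% of a library's count. Most of this came from Lars2, Gm13340 and Gm20594, which together took 3.92% to 18.5%.

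Fewer genes were detected in c-Myc-high than in c-Myc-low libraries. In 1200000 counts drawn from each library, 11755 ± 106 genes (SD, n = 2) had a count in primary c-Myc-high and 16163 ± 130 (SD, n = 2) in primary c-Myc-low libraries. The metastatic groups gave 14473 ± 1858 (SD, n = 3) and 17553 ± 819 (SD, n = 3). The mean difference within sites was -3744 genes, with an exact two-sided permutation p = 0.0167 over 120 arrangements, the smallest these can give. Without the drawing, the genes with 10 or more counts differed by -4070 (exact two-sided p = 0.0167). Total counts differed by -1738400 (exact two-sided p = 0.183). The reads implied by RPKM averaged 19.32 and 28.14 times 1e6 in primary c-Myc-high and c-Myc-low libraries, and 23.8 and 27.88 in metastatic ones. Drawing equal counts does not equalise RNA input or the variety of molecules in amplified libraries. A property of the cells and one of the libraries therefore cannot be told apart here.

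**Figure D1:**
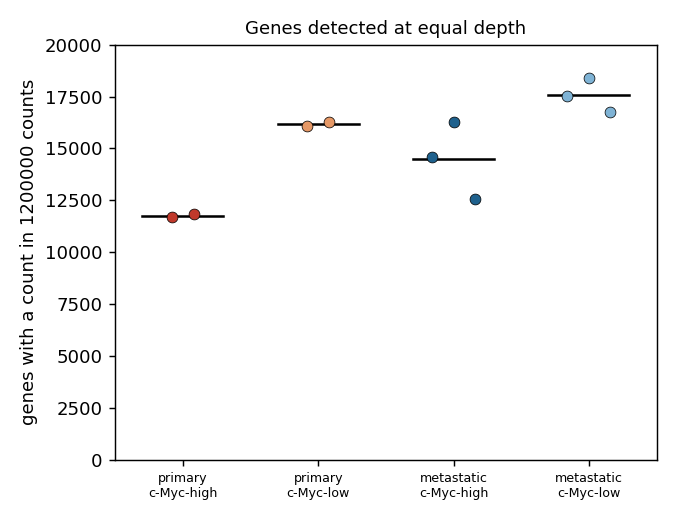
Genes with at least 1 count after 1200000 counts were drawn from each library (vertical axis, number of genes) in the 4 groups, with points for libraries and lines for group means. Both primary c-Myc-high libraries lie at 11680 and 11830, below the primary c-Myc-low libraries at 16071 and 16255.

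Metastatic and primary c-Myc-high cells were compared first, as the contrast named in the study's design. Genes of the stratified epidermis were lower in the metastatic cells, and some genes of leukocytes were called higher. Of 16272 genes tested, 104 were higher and 231 lower in metastatic cells. A fit of these 2 groups alone called 0 genes, so the calls depend on the spread shared with the c-Myc-low libraries. The balance turned with DESeq2 (1989 higher and 1042 lower), without metastatic c-Myc-high replicate 3 (350 and 206) and at an unadjusted p under 0.05 (2622 and 1349). Limma-voom with quality weights gave 0 higher and 91 lower, and limma-trend on RPKM 6 and 83. Among 16 keratinocyte marker genes 13 fell, and 15 did when p-values were adjusted over the list alone. The median log2 fold change was -9.74 (camera, adjusted p = 1.03e-34, and adjusted p = 0.00903 with an estimated correlation). Krt1, a keratin of differentiating epidermis, had a mean of 14960 CPM ± 8267 (SD, n = 2) in primary and 10.02 CPM ± 3.67 (SD, n = 3) in metastatic cells. Its log2 change was -10.55 (SE 1.24, adjusted p = 0.00317). Krt14, a keratin of basal cells, changed by -10.33 (SE 1.37, adjusted p = 0.0056).

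The genes with the largest decreases included further epidermal genes. Lypd3, a surface protein of keratinocytes, averaged 728 CPM ± 648 (SD, n = 2) in primary and 0 in metastatic c-Myc-high cells, at least 1920-fold lower (adjusted p = 0.00443). It lies on chromosome 7 from 24636550 to 24641118 (GRCm38). Lce1m, of the late cornified envelope, had 379 CPM ± 380 (SD, n = 2) in primary cells and was at least 1000-fold lower (adjusted p = 0.00492). Dsc1, a desmosomal cadherin, was at least 607-fold lower (adjusted p = 0.00535). The metallothionein gene Mt4, at 466 CPM ± 658 (SD, n = 2) in primary cells, was by this mean at least 1230-fold lower (adjusted p = 0.043). Hoxa7, Slc16a14 and Esyt3 had 318 ± 398, 242 ± 108 and 207 ± 276 CPM there (SD, n = 2). They were at least 840-, 638- and 546-fold lower (adjusted p = 0.00856, 0.00748 and 0.0177). Bpifc, at 911 CPM ± 1260 (SD, n = 2) in primary cells, was lower by a ratio of 3160 (95% interval 565 to 125000, adjusted p = 0.00995). Ccl27a, a chemokine of skin, fell by 7.50 on the log2 scale (adjusted p = 0.0188). The transcripts standing for Dclre1c and Prpf18 had 319 ± 450 and 288 ± 372 CPM (SD, n = 2) in primary cells. By these means they were at least 843- and 759-fold lower (adjusted p = 0.0373 and 0.0472). With all transcripts summed these 2 genes no longer passed, at -2.45 and -3.59 (adjusted p = 0.23 and 0.0781).

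Of 10 pan-leukocyte genes Cd53, Laptm5 and Ptprc, 3 in all, rose in metastatic c-Myc-high cells, and 9 did when adjusted over the list alone, with a median of 7.56 (camera, adjusted p = 5.52e-06, and adjusted p = 0.839 with an estimated correlation). Cd53, a tetraspanin of leukocytes on chromosome 3 from 106759921 to 106790149, averaged 252 CPM ± 268 (SD, n = 3) against 0, at least 333-fold higher (adjusted p = 0.0378). Ptprc, which encodes the pan-leukocyte antigen CD45, had 405 CPM ± 377 (SD, n = 3) against 1.92 ± 2.71 (SD, n = 2), a log2 change of 7.45 (SE 1.71, adjusted p = 0.0481). Laptm5, of lysosomes in blood cells, rose by a ratio of 490 (95% interval 167 to 2380, adjusted p = 0.0465). In the alternatives tried Ptprc passed in 7 of 23 and Cd53 in 10 of 23, with adjusted p from 3.75e-06 to 0.352 and from 3.8e-06 to 0.33.

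Of 11 B cell genes 1 rose, and 10 did when adjusted over the list alone. The list's median was 7.79, or 7.28 with members at 0 counts set to their bound (camera, adjusted p = 2.78e-05, and adjusted p = 0.839 with an estimated correlation). Cr2, a complement receptor, rose by 7.79 (SE 1.61, adjusted p = 0.032). Of 14 T cell genes none passed over all genes and 13 did when adjusted over the list alone, with a median of 7.50, or 5.11 with bounds (camera, adjusted p = 8.76e-05, and adjusted p = 0.839 with an estimated correlation). Of 31 interferon response genes only Ifit1 rose, at least 69.3-fold (adjusted p = 0.0473). Adjusted over the list alone, 11 rose and 1 fell, with a median of 4.59, or 3.33 with bounds (camera, adjusted p = 0.000204, and adjusted p = 0.747 with an estimated correlation). None of 10 MHC class II genes passed over all genes and 6 did when adjusted over the list alone, with a median of 7.44, or 7.04 with bounds (camera, adjusted p = 0.00728, and adjusted p = 0.839 with an estimated correlation). Without primary c-Myc-high replicate 2, or in the 8 deepest libraries, the latter list did not pass (adjusted p = 0.32 and 0.0659). Summed CPM of the pan-leukocyte list was 1341, 6370 and 318 in metastatic c-Myc-high replicates 1, 2 and 3, and 93.1 and 36.9 in primary replicates 1 and 2.

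**Figure D2:**
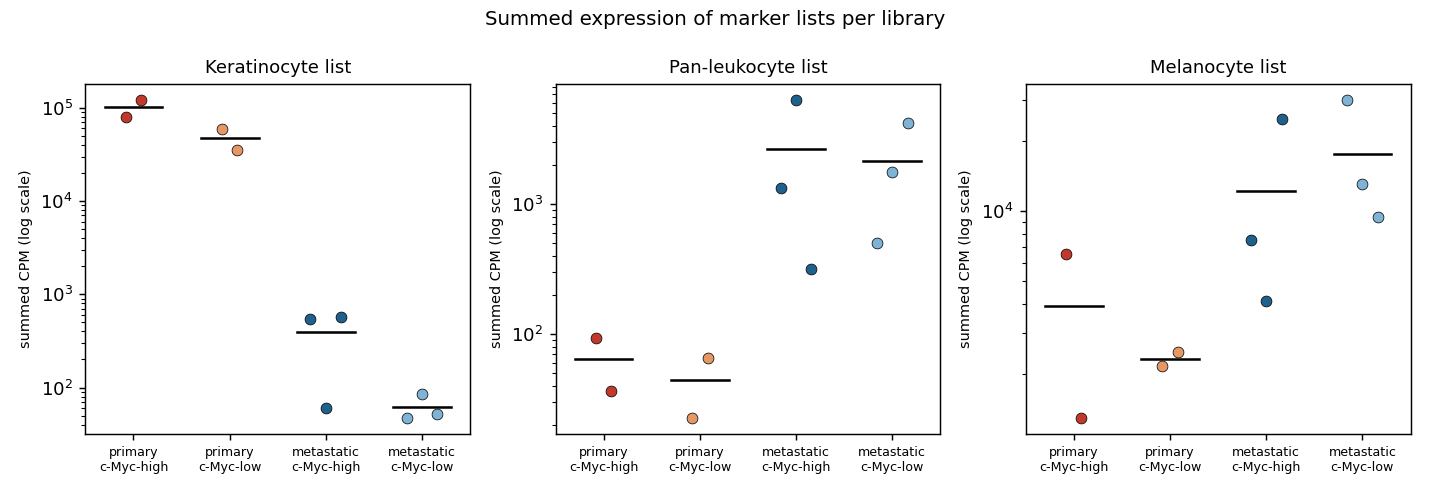
Summed CPM (vertical axes, log scale) of the keratinocyte, pan-leukocyte and melanocyte lists in the 4 groups, with points for libraries and lines for group means. Keratinocyte sums are at least 35310 CPM in the primary libraries and at most 575 CPM in the metastatic ones.

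Single genes of the adhesion and homing lists also passed. Whether their transcripts came from leukocytes or from melanoma cells was not tested. The integrin genes Itga4 and Itgb3 rose by 6.01 and 8.31 on the log2 scale (adjusted p = 0.0214 and 0.0487), within an extracellular matrix list of which 2 of 39 rose, or 7 with 4 lower when adjusted over the list alone (camera, adjusted p = 0.924). Itgb3 had 2 counts in primary cells, a ratio of 320 (95% interval 88.5 to 2650). Of 14 chemokines and receptors of lymph node homing 2 rose and 1 fell, or 5 and 1 when adjusted over the list alone, with a median of 5.50, or 4.42 with bounds (camera, adjusted p = 0.0592, and adjusted p = 0.839 with an estimated correlation). The receptors S1pr1 and Cxcr4 rose by ratios of 185 (95% interval 51.0 to 1530, adjusted p = 0.0319) and 104 (95% interval 35.3 to 504, adjusted p = 0.0427). Ceacam1, an adhesion molecule, and Ehd3, of endosome traffic, were at least 179- and 105-fold higher (adjusted p = 0.0321 and 0.0123). The transcript standing for Fyb, an adaptor of T cells, was at least 120-fold higher (adjusted p = 0.0378), and with transcripts summed the gene's log2 change was 4.79 (adjusted p = 0.0449). The glycolytic regulator Pdk2 was at least 74.7-fold higher (adjusted p = 0.0485), and the cell cycle inhibitor Cdkn1a fell by 3.63 (adjusted p = 0.0299), with a value of -2.16 when transcripts were summed (adjusted p = 0.134).

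Several further calls were made on 1 transcript and did not pass with all transcripts of the gene summed. The transcripts standing for Msl1, Cd97, Gtpbp2, Zeb1, Mcc and Xpo1 were at least 144-, 140-, 135-, 133-, 117- and 111-fold higher (adjusted p = 0.0115, 0.0428, 0.0419, 0.0223, 0.0353 and 0.00928). With transcripts summed their log2 changes were 0.10, 3.03, 3.35, 3.42, 1.34 and 0.71 (adjusted p = 0.944, 0.134, 0.0723, 0.0916, 0.418 and 0.479). Summing transcripts kept 217 of the 231 lower and 60 of the 104 higher calls. DESeq2 called 3031 genes, limma-voom 534, a fit of only the 2 groups 0, and a fit without both libraries rich in salivary gland transcripts 0. Leaving out primary c-Myc-high replicate 2 gave 953 genes, metastatic c-Myc-high replicates 1, 2 and 3 gave 89, 197 and 556, primary c-Myc-low replicates 1 and 2 gave 153 and 160, and metastatic c-Myc-low replicates 1, 2 and 3 gave 202, 168 and 201. Of the 21 called genes named by rule, 9 and 14 stayed called without primary c-Myc-high replicates 1 and 2, 12 and 14 without primary c-Myc-low replicates 1 and 2, 8, 12 and 18 without metastatic c-Myc-high replicates 1, 2 and 3, and 14, 11 and 13 without metastatic c-Myc-low replicates 1, 2 and 3.

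Myc itself, on chromosome 15 from 61985391 to 61990374, was not called between any groups. Its mean was 404 CPM ± 503 (SD, n = 2) in primary c-Myc-high, 169 ± 136 (SD, n = 2) in primary c-Myc-low, 179 ± 53.3 (SD, n = 3) in metastatic c-Myc-high and 172 ± 92.6 (SD, n = 3) in metastatic c-Myc-low cells. The log2 change between c-Myc classes was 1.26 (SE 1.16, adjusted p = 0.67) in primary and 0.06 (SE 0.93, adjusted p = 1) in metastatic cells. Between sites it was -1.17 (SE 1.03, adjusted p = 0.484) in c-Myc-high and 0.03 (SE 1.04, adjusted p = 1) in c-Myc-low cells. Of 52 canonical Myc targets only the single transcript of Xpo1 passed between sites in c-Myc-high cells (camera, adjusted p = 0.613), and 0 of 10 genes of the Myc and MAX network did (camera, adjusted p = 0.596).

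AMPK, an energy-sensing kinase, and oxidative stress are named in the study's title. Of its subunit genes, Prkaa1 (chromosome 15, 5143861 to 5181899) changed by 0.30 (SE 0.84, adjusted p = 0.854) between metastatic and primary c-Myc-high cells. Prkaa2 gave 2.61 (SE 1.80, adjusted p = 0.37), Prkab1 2.16 (SE 1.64, adjusted p = 0.415) and Prkag1 -0.02 (SE 0.93, adjusted p = 1). With transcripts summed Prkab1 gave -1.88 (adjusted p = 0.259). None of 22 AMPK subunit and upstream genes (camera, adjusted p = 0.914), 33 AMPK substrates (camera, adjusted p = 0.963) or 48 antioxidant genes (camera, adjusted p = 0.924) passed, also when adjusted over the list alone. Nfe2l2, a regulator of antioxidant genes, gave -1.10 (SE 0.77, adjusted p = 0.374). In simulated data for this comparison edgeR recovered no log2 change of 4 and DESeq2 30% of them, the latter with 67 false calls among 161, so differences of that size were not detectable with edgeR here.

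**Figure D3:**
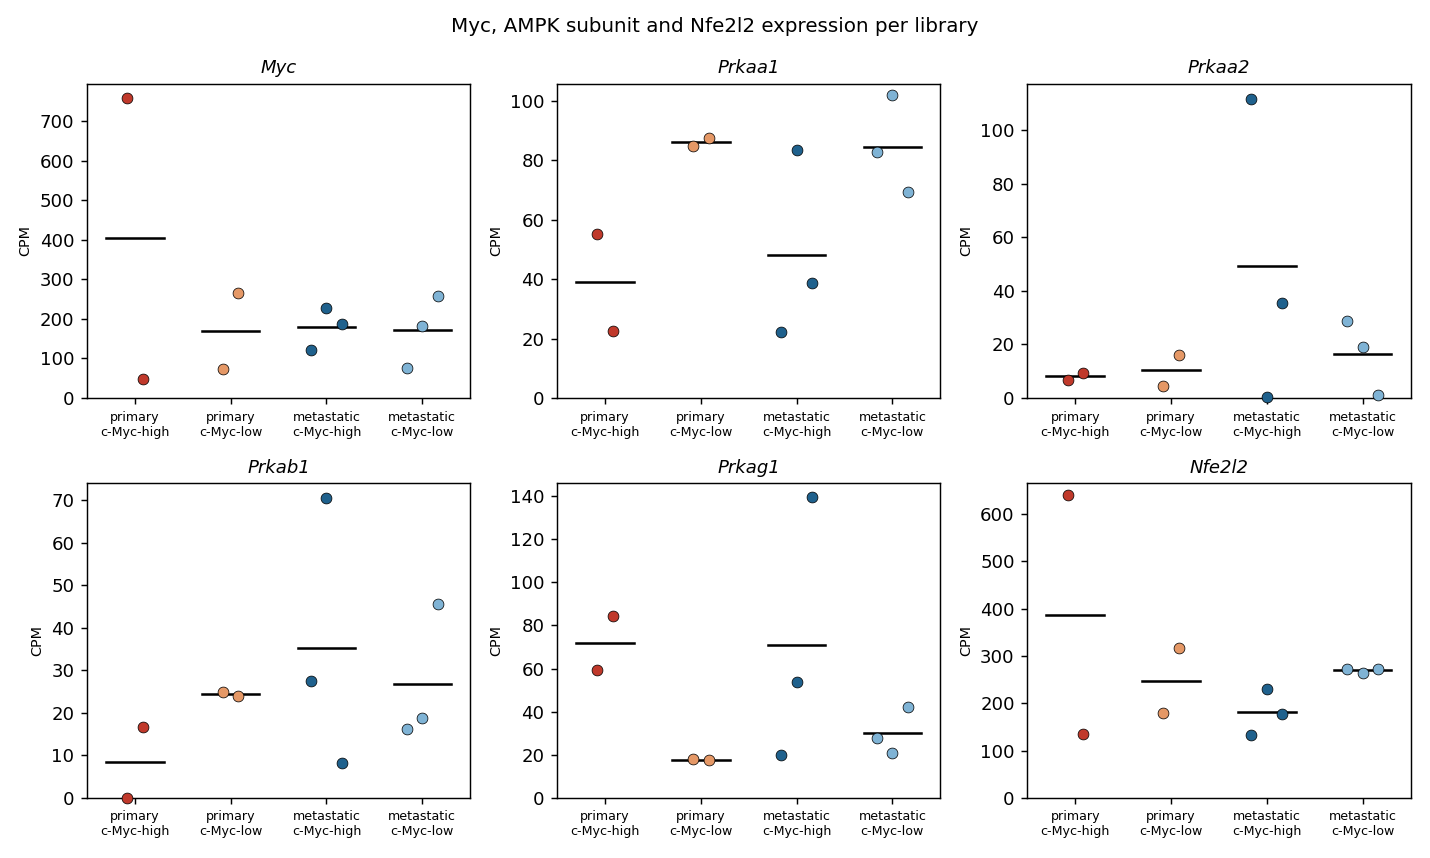
Expression of Myc, the AMPK subunit genes Prkaa1, Prkaa2, Prkab1 and Prkag1, and Nfe2l2 (vertical axes, CPM) in the 4 groups, with points for libraries and lines for group means. Myc averages 404 CPM in primary c-Myc-high libraries and 169 to 179 CPM in the others, with an SD of 503 in the former.

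Pigment cell genes did not pass between metastatic and primary c-Myc-high cells. Dct gave 2.96 (SE 1.43, adjusted p = 0.226), Tyr 1.89 (SE 1.14, adjusted p = 0.311), Mitf 1.46 (SE 1.18, adjusted p = 0.446) and Sox10 0.49 (SE 1.02, adjusted p = 0.793). Of 33 melanocyte genes 29 had positive values and 0 passed, also when adjusted over the list alone, with a median of 1.66 (camera, adjusted p = 0.0232, and adjusted p = 0.839 with an estimated correlation). The call was lost without primary c-Myc-high replicate 2 or metastatic c-Myc-high replicate 3 (adjusted p = 0.583 and 0.323). The median was 3.89 without primary c-Myc-high replicate 1 (adjusted p = 0.000176), and without the libraries rich in salivary transcripts 0.27 (adjusted p = 0.867). In the 8 deepest libraries the median was 0.47 and the direction of the test turned (adjusted p = 0.938). Ribosome biogenesis genes had a median of -0.54 (camera, adjusted p = 0.0232) and mitotic genes of -0.98 (camera, adjusted p = 0.0329), both with adjusted p = 0.839 with an estimated correlation and with 0 called, also when adjusted over the list alone. Without primary c-Myc-high replicate 1 the mitotic median was 1.12 (adjusted p = 0.846), and without metastatic c-Myc-high replicate 1 or 2 its adjusted p was 0.161 and 0.0532. Ribosome biogenesis was not called without primary c-Myc-high replicate 1 or 2 or metastatic c-Myc-high replicate 1 (adjusted p = 0.226, 0.052 and 0.0821), nor without the libraries rich in salivary transcripts (adjusted p = 0.0523).

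The same site comparison in c-Myc-low cells served as its background. Keratinocyte genes were again lower in metastatic cells, and some B cell genes were called higher. In all 26 genes were higher and 199 lower. DESeq2 gave 825 higher and 573 lower, limma-voom with quality weights 1944 and 1373, and an unadjusted p under 0.05 gave 1306 and 885. Without primary c-Myc-low replicate 1 or 2, or metastatic c-Myc-low replicate 1, 2 or 3, edgeR called 0 higher genes. Of 16 keratinocyte genes 14 fell, and 16 did when adjusted over the list alone, with a median of -9.62 (camera, adjusted p = 9.69e-47, and adjusted p = 0.0107 with an estimated correlation). Krt79, a keratin of hair follicle and gland ducts on chromosome 15 from 101929332 to 101940324, averaged 477 CPM ± 34.3 (SD, n = 2) in primary and 0.138 ± 0.125 (SD, n = 3) in metastatic cells, lower by a ratio of 3690 (95% interval 1020 to 30400, adjusted p = 0.00245). Fgfbp1 and Clca5 were lower by ratios of 6910 (95% interval 1240 to 273000, adjusted p = 0.00688) and 3280 (95% interval 907 to 27100, adjusted p = 0.00245). Calm4, a calcium-binding protein of epidermis, fell by 11.72 (SE 1.44, adjusted p = 0.00367). Sh3rf2, Cyp2b10, Lipm and Slc34a2 were at least 783-, 698-, 636- and 505-fold lower (adjusted p = 0.0135, 0.0375, 0.0163 and 0.0365). The transcripts standing for Gpr115 and Arhgef4 were at least 1020- and 655-fold lower (adjusted p = 0.00656 and 0.0127), and with transcripts summed these genes gave -9.62 and -4.30 (adjusted p = 0.00271 and 0.0171).

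Of 11 B cell genes Ms4a1, Cr2 and Faim3, 3 in all, rose in metastatic c-Myc-low cells, and 10 did when adjusted over the list alone, with a median of 8.29, or 7.34 with bounds (camera, adjusted p = 1.54e-11, and adjusted p = 0.33 with an estimated correlation). Ms4a1, which encodes CD20, rose by a ratio of 1570 (95% interval 282 to 62100, adjusted p = 0.0375). Ptprc rose by 8.06 (SE 1.75, adjusted p = 0.047), the only one of 10 pan-leukocyte genes past the threshold over all genes, while 10 passed when adjusted over the list alone (camera, adjusted p = 1.29e-09, and adjusted p = 0.33 with an estimated correlation). The transcript standing for Fyb was at least 386-fold higher (adjusted p = 0.0252), with 5.51 when transcripts were summed (adjusted p = 0.0366). Slamf6, Sla, Cxcr4 and Gimap5 were at least 302-, 183-, 109- and 107-fold higher (adjusted p = 0.0441, 0.0452, 0.0163 and 0.0267), and Themis2 was higher by a ratio of 934 (95% interval 167 to 36900, adjusted p = 0.0457). Faim3 was at least 138-fold higher, Itgal higher by a ratio of 1060 (95% interval 191 to 42000), both with adjusted p = 0.0497, and the transcript of Cnp at least 198-fold higher (adjusted p = 0.0205). With transcripts summed these 3 no longer passed (adjusted p = 0.0684, 0.0704 and 0.166).

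Melanocyte genes had a median of 3.15 in this comparison, with 30 of 33 positive (camera, adjusted p = 1.37e-07, and adjusted p = 0.466 with an estimated correlation). None passed over all genes, and 6 were higher and 1 lower when adjusted over the list alone. Pmel, a melanosome protein, gave 3.66 (SE 0.86, adjusted p = 0.0642) and Sox10 3.96 (SE 1.21, adjusted p = 0.158). Of 39 extracellular matrix genes Itga4 rose by 5.99 (adjusted p = 0.0219), and 12 were higher and 3 lower when adjusted over the list alone (camera, adjusted p = 0.00273, and adjusted p = 0.33 with an estimated correlation). Egln3, a hypoxia-induced hydroxylase, fell by 4.88 (adjusted p = 0.0287) among 23 hypoxia genes, also the 1 called when adjusted over the list alone (camera, adjusted p = 0.0423, and adjusted p = 0.33 with an estimated correlation). The hypoxia list was not called without primary c-Myc-low replicate 2, metastatic c-Myc-high replicate 1 or 2, or metastatic c-Myc-low replicate 2 or 3 (adjusted p = 0.0996, 0.0528, 0.0529, 0.0538 and 0.143). DESeq2 called 1398 genes, limma-voom 688, and the fit of only these 2 groups 1619. Leaving out primary c-Myc-low replicates 1 and 2 gave 84 and 95 genes, and metastatic c-Myc-low replicates 1, 2 and 3 gave 16, 15 and 17. Of the 21 called genes named by rule, 5 and 7 stayed called without primary c-Myc-low replicates 1 and 2, 2, 2 and 3 without metastatic c-Myc-low replicates 1, 2 and 3, 18 and 18 without primary c-Myc-high replicates 1 and 2, and 14, 20 and 19 without metastatic c-Myc-high replicates 1, 2 and 3.

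The groups of the site comparisons in c-Myc-high and c-Myc-low cells shared no libraries. Both comparisons came from 1 fit of all 10 libraries with a shared estimate of spread, so their calls were not independent. Their numbers of calls should not be compared either. Fits of only the groups compared gave 0 genes in c-Myc-high and 1619 in c-Myc-low cells. They had 153 lower calls in common, where independent lists of the same sizes would share 2.83, and 9 higher calls, where 0.166 would be shared. The values for independent lists are thus a reference only and no test. Of the c-Myc-high calls, 228 of 231 lower and 95 of 104 higher genes had the same sign in c-Myc-low cells. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.615.

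Between c-Myc-high and c-Myc-low cells of primary tumours edgeR called 0 genes, with 1914 at an unadjusted p under 0.05. DESeq2 called 518, limma-voom 0, limma-voom with quality weights 1 and limma-trend on RPKM 10. The lowest p-values belonged to single transcripts of Strn3, Sel1l, Xpo1, Msl1 and Rnf14 with 0 counts in c-Myc-high cells (adjusted p = 0.187 each). With transcripts summed Strn3 gave 0.21 and Msl1 -0.09 (adjusted p = 0.958 and 0.997). In the other direction they were Dennd2c, Trim30a, Glis3, Mlycd and Prpf18 (adjusted p = 0.417 each), of which Dennd2c gave 2.01 with transcripts summed (adjusted p = 0.473). Mlycd, malonyl-CoA decarboxylase of fatty acid metabolism, gave 4.63 (SE 1.18). Oxidative phosphorylation genes had a median of 0.68 with 47 of 69 positive and ribosome biogenesis genes of 0.69 with 33 of 49 positive, none called, also when adjusted over the list alone (camera, both adjusted p = 0.0303, and both adjusted p = 0.866 with an estimated correlation). The strict count filter ended both calls (adjusted p = 0.0602 each), as did the 8 deepest libraries (adjusted p = 0.136 and 0.0894). Leaving out primary c-Myc-high replicate 1 or 2 ended both calls, with medians of -0.07 and 0.22 for oxidative phosphorylation (adjusted p = 0.124 and 0.126) and 0.16 and 0.65 for ribosome biogenesis (adjusted p = 0.292 and 0.0888). The latter call also ended without primary c-Myc-low replicate 2 (adjusted p = 0.175). Without primary c-Myc-high replicate 2, which had the lowest total count, edgeR called more genes, as it did in the 8 deepest libraries. Both fits keep only replicate 1 of primary c-Myc-high, so these calls have no spread within that group behind them.

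In metastases edgeR likewise called 0 genes between c-Myc-high and c-Myc-low cells, with 732 at an unadjusted p under 0.05. DESeq2 called 88, limma-voom with or without quality weights 0 and limma-trend on RPKM 2. Salivary kallikrein genes led the list of higher values. Klk1, on chromosome 7 from 44225360 to 44229618, averaged 4870 CPM ± 4120 (SD, n = 3) against 1.11 ± 0.852 (SD, n = 3) and gave a log2 change of 12.05 (SE 2.10, adjusted p = 0.791). Klk1b5 and Klk1b4, whose sequences are close to that of Klk1 so that reads may be shared, gave 11.94 and 10.89 (adjusted p = 0.791 and 0.793). Esrp2, an epithelial splicing regulator, gave 6.72 (adjusted p = 0.793), and Ldhd had 135 counts against 0 (adjusted p = 0.793). Single transcripts of Tfdp2, Fam118b, Nbl1, Ifi202b and Klhl26 had the lowest p-values in the other direction (adjusted p = 0.882, 0.882, 1, 1 and 1). With transcripts summed Tfdp2, Fam118b and Klhl26 gave 0.09, -1.61 and 0.71 (adjusted p = 1 each), and Esrp2 and Ldhd gave 4.10 and 1.96 (adjusted p = 0.617 and 1).

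Other salivary gland transcripts were abundant in 2 of these libraries. Of 31 salivary gland genes, a list made after the kallikreins were seen, 16 reached 100 CPM in metastatic c-Myc-high replicate 1 and 10 in replicate 3. They took 11.7% and 0.994% of the count there, and 0.00821% in replicate 2. Metastatic c-Myc-low replicate 2 had 4 such genes and 0.110%. In replicate 1 Bpifa2, a parotid secretory protein, had 75065 CPM and Amy1, salivary amylase, 35061 CPM, and in replicate 3 Amy1 had 6183 CPM and Car6 3107 CPM.

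**Figure D4:**
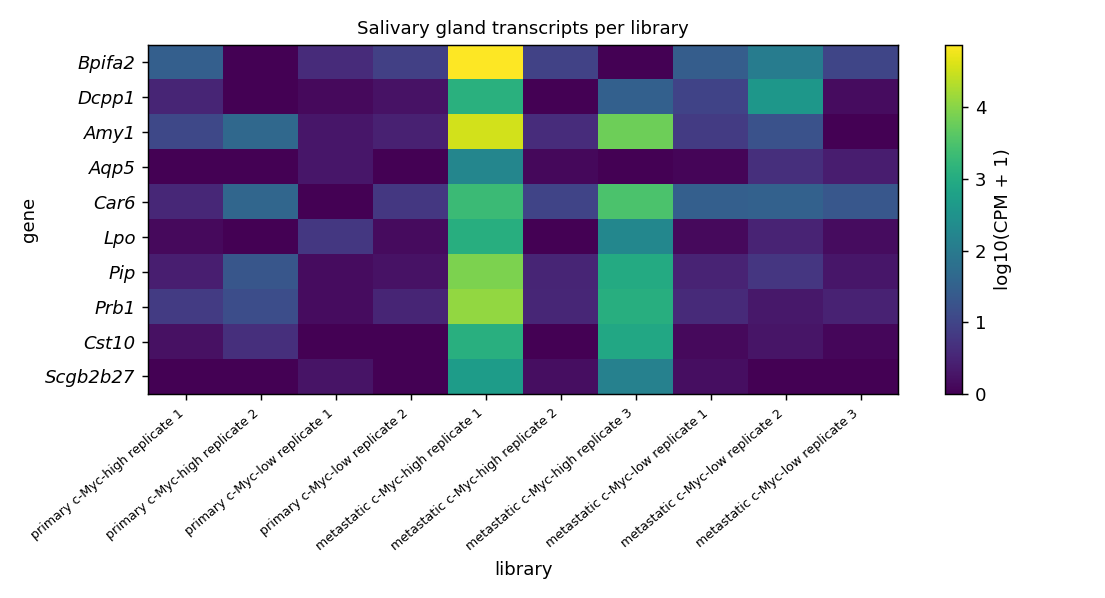
Expression of 10 salivary gland genes (vertical axis) in the 10 libraries (horizontal axis), with colour for log10(CPM + 1). Metastatic c-Myc-high replicates 1 and 3 stand out, with Amy1 at 35061 and 6183 CPM.

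Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were positive for 62 of 69 members between c-Myc-high and c-Myc-low metastatic cells. Their median was 0.73 (camera, adjusted p = 1.76e-08, and adjusted p = 0.289 with an estimated correlation), and 0 were called, also when adjusted over the list alone. Ndufa2 and Ndufb8, of complex I, gave 2.63 (SE 1.05, adjusted p = 1) and 2.24 (SE 1.03, adjusted p = 1). Both scalings kept the sign, and DESeq2's size factors moved the median of all genes by 0.11. ER stress genes had a median of 0.59 (camera, adjusted p = 0.00446, and adjusted p = 0.641 with an estimated correlation), with Chac1 at 4.09 (SE 1.48, adjusted p = 1). Fibroblast genes had a median of -1.52 with 13 of 13 negative (camera, adjusted p = 0.00763, and adjusted p = 0.998 with an estimated correlation). The keratinocyte list had a median of 0.44 (camera, adjusted p = 0.0195, and adjusted p = 0.998 with an estimated correlation). Salivary transcripts were abundant in 2 of the 3 c-Myc-high libraries. Without those 2 libraries the ER stress and keratinocyte medians were -0.33 and -0.36 (camera, adjusted p = 0.87 and 0.573), and the fibroblast median was -1.11 (camera, adjusted p = 0.862). Leaving out metastatic c-Myc-high replicate 1 alone ended the ER stress, fibroblast and keratinocyte calls (adjusted p = 0.129, 0.275 and 0.129). The keratinocyte call also ended without metastatic c-Myc-high replicate 3 or metastatic c-Myc-low replicate 1 or 3 (adjusted p = 0.298, 0.0779 and 0.0584). Leaving out metastatic c-Myc-high replicate 2 gave 13 called genes.

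Averaged over both sites, edgeR called 0 genes for c-Myc status, with 2160 at an unadjusted p under 0.05, DESeq2 called 640, and limma-voom and limma-trend on RPKM 0. Oxidative phosphorylation genes had a median of 0.84 with 51 of 69 positive (camera, adjusted p = 1.95e-06, and adjusted p = 0.516 with an estimated correlation). Ribosome biogenesis genes had a median of 0.57 with 38 of 49 positive (camera, adjusted p = 0.00109, and adjusted p = 0.893 with an estimated correlation). Among the latter Nop16 gave 3.12 (SE 0.85, adjusted p = 0.284) and Npm1, nucleophosmin, 3.78 (SE 1.22, adjusted p = 0.284). No member of either list was called, also when adjusted over the list alone. Without primary c-Myc-high replicate 1 the medians were 0.25 for oxidative phosphorylation and 0.35 for ribosome biogenesis (camera, adjusted p = 3.49e-05 and 0.0252), over all alternatives with adjusted p from 1.73e-07 to 0.00124 and from 8.68e-05 to 0.0252. Salivary kallikreins had the lowest p among higher genes here too, with Klk1b5, Klk1 and Klk1b4 at 8.62, 9.51 and 8.60 (adjusted p = 0.239, 0.239 and 0.284). Lgals7 and Mlycd gave 3.61 and 3.29, and the transcripts standing for Alcam and Fam129a -5.93 and -5.30 (adjusted p = 0.284, 0.284, 0.239 and 0.239). With transcripts summed Alcam and Fam129a gave -0.34 and -1.65 (adjusted p = 0.92 and 0.305). Without primary c-Myc-high replicate 2, 36 genes were called.

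The difference between sites in the effect of c-Myc status was tested as an interaction. By edgeR 0 genes passed, with 1122 at an unadjusted p under 0.05. DESeq2 called 127, and limma-voom and limma-trend on RPKM 0. The lowest p belonged to the transcript of Strn3 at 11.71 (SE 1.74, adjusted p = 0.398), and with transcripts summed the gene gave -0.84 (adjusted p = 0.913). Myc gave -1.20 (SE 1.48, adjusted p = 0.919) and Sox10 -3.46 (SE 1.47, adjusted p = 0.712). Simulated interactions of up to log2 6 were recovered at 0% by edgeR and those of 10 at 30%. DESeq2 recovered 36% of those of 6, with 87 false calls among 149.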

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

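The tests of keratinocyte, leukocyte and salivary gland RNA and of spillover between libraries were chosen only after the results they concern had been seen.

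Extracellular matrix and fibroblast genes stood out because the effect of c-Myc status differed between sites by a test of that difference. The extracellular matrix list had a median log2 difference of -1.10 with 27 of 39 negative, and the fibroblast list one of -3.77 with 12 of 13 negative (camera, adjusted p = 0.00224 and 0.000562). With an estimated correlation neither passed, both with adjusted p = 0.981, and no member was called, also when adjusted over the list alone. Fn1, fibronectin, gave -4.08 (SE 1.31, adjusted p = 0.712), and the collagen genes Col1a1 and Col3a1 gave -4.92 and -4.22 (adjusted p = 0.761 and 0.767). The matrix call ended without primary c-Myc-low replicate 1 (adjusted p = 0.0561). The fibroblast call ended without that library (adjusted p = 0.0561), and without primary c-Myc-high replicate 2 the median was 1.78 (adjusted p = 0.937). It also ended in the 8 deepest libraries, with a median of 1.53 (adjusted p = 0.999), and without the libraries rich in salivary transcripts, with -2.97 (adjusted p = 0.135).

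Lower epidermal and higher leukocyte transcripts in metastatic cells were weighed first. The choice of 1 transcript per gene is argued against for the lower genes as a whole, since 93.9% of the 231 were called lower again with transcripts summed. The number of calls under summing, but not the overlap, was known when this test was written. Of the 104 higher genes, which the test did not cover, 57.7% were called higher again. For them the choice of transcript stays open. Keratinocyte RNA in the libraries from skin is a candidate explanation, with 14 of 16 keratinocyte genes over 10 times higher in both primary than in both metastatic group means, Krt1 at 14960 CPM and Krt5 at 12050 CPM in primary c-Myc-high cells, and 1 of the 16 also in another list. Leukocyte RNA in the lymph node libraries may likewise account for the higher genes, with a median above 2 in both site comparisons for 7 of 7 leukocyte lists, and Cd52 at 303 CPM and Ptprc at 405 CPM in metastatic c-Myc-high cells. In the GFP-positive sort both would have to pass the gate or follow it as free RNA, while cells without the reporter enter the GFP-negative sort directly, and a difference in the melanoma cells of each site stays open, untested.

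High kallikrein transcripts in metastatic c-Myc-high cells were weighed next. Salivary gland RNA is a candidate explanation, since 12 of 20 salivary genes outside the Klk1 family reached 100 CPM in replicate 1, with Bpifa2 at 75065 CPM and Amy1 at 35061 CPM. Of the 31 listed genes 5 exceeded 10 CPM in a primary library, and the GFP gate should exclude gland cells unless they carried the reporter. Spillover from replicate 1 is argued against as the source in replicate 3, since the log2 ratio between both libraries had an SD of 3.89 over 16 genes, where a single source would keep it about constant. Why replicate 2 had far less of these transcripts (Klk1b3 at 14.7 CPM against 856 CPM in replicate 1), and whether a difference between c-Myc-high and c-Myc-low cells contributed, stay open and untested.

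Oxidative phosphorylation genes, higher on balance in metastatic c-Myc-high cells, were weighed last. For a general shift of short, abundant transcripts, 10000 lists matched on expression and length were drawn. The median of 0.76 for 68 members with a known length lay at percentile 99.7 of these. Their genes were drawn singly, without the correlation between members of a pathway. Camera did not call the list once such a correlation was estimated. The percentile therefore cannot exclude such a shift as the whole cause. The matched lists had a median of 0.43, so part of the value may be shared with them. Without the 2 libraries rich in salivary transcripts the median was 0.55 (bootstrap interval over members 0.40 to 0.87), above the bound of 0.5 set beforehand for excluding gland RNA. That bound was no fair test with 1 c-Myc-high library left and an interval reaching below it, so gland RNA and another difference cannot be told apart here. Reads shared with processed pseudogenes of these genes, and an effect of c-Myc status, also stay open, untested.

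Per library the mean log2 CPM of the oxidative phosphorylation list was 4.72, 4.71 and 4.97 in metastatic c-Myc-high replicates 1, 2 and 3 and 4.65, 3.86 and 4.31 in metastatic c-Myc-low replicates 1, 2 and 3. The primary c-Myc-high replicates 1 and 2 had 4.37 and 4.50, and the primary c-Myc-low replicates 1 and 2 had 4.35 and 4.45. Pooled within both sites, the c-Myc classes differed by 0.28 (exact two-sided permutation p = 0.0667, 120 arrangements). The primary classes overlapped in these means, although the list's median log2 change there was 0.68, and the reason was not tested. In metastases c-Myc-low replicate 2 had the lowest value, and c-Myc-low replicate 1 lay near c-Myc-high replicates 1 and 2.

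For calls between c-Myc-high and c-Myc-low metastatic libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. With edgeR the real split gave 0 and the highest other 0, so all 10 gave as many by construction. With DESeq2 the real split gave 88 and the highest other 209, from metastatic c-Myc-high replicates 1 and 3 with metastatic c-Myc-low replicate 1 against the rest, and 4 of the 10 gave as many as the real one. For c-Myc status over both sites, edgeR called 0 in the real split and 0 in the highest other. All 60 within-site splits gave as many by construction, so this test decides nothing about chance. The real edgeR and DESeq2 counts were known when these tests were written.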

How the results depend on the processing

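The fits of the 8 deepest libraries and without the 2 libraries rich in salivary transcripts were chosen only after the results had been seen. Counts of called genes depended on the processing in each comparison; where no reason is given, the cause was not tested. For metastatic against primary c-Myc-high cells, 335 as designed, both other scalings (313 and 328) and the strict filter (446) stayed within 1.5 times. No count filter gave 985, DESeq2 3031, limma-voom 534 and 91 with quality weights, only the groups compared 0, transcripts summed 667, limma-trend on RPKM 89, the 8 deepest libraries 2305 and no libraries rich in salivary transcripts 0. Leaving out 1 library gave 89 to 953. For c-Myc-low cells, 225 as designed, both scalings (228 and 227), the strict filter (247) and no libraries rich in salivary transcripts (327) stayed within 1.5 times. No filter gave 586, DESeq2 1398, limma-voom 688 and 3317 with quality weights, only the groups compared 1619, summing 355, RPKM 396, the 8 deepest libraries 558, and leaving out 1 library 15 to 304.

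For c-Myc status the edgeR count of 0 in primary cells became 12 with no filter, 518 with DESeq2, 1 by limma-voom with quality weights, 10 on RPKM, 1109 in the 8 deepest libraries and 0 to 53 with 1 library left out. In metastases it became 3, 88 and 2 with no filter, DESeq2 and RPKM, and 0 to 13 with 1 library left out. Over both sites it became 29 with no filter, 640 with DESeq2, 485 in the 8 deepest libraries and 0 to 36 with 1 library left out. The interaction count became 3, 127 and 269 with no filter, DESeq2 and the 8 deepest libraries, and stayed at 0 with any 1 library left out. Leaving out a library of a pair leaves 1 sample, assumed to vary like the other groups. The 8 deepest libraries likewise hold only replicate 1 of primary c-Myc-high. The fit without libraries rich in salivary transcripts holds only replicate 2 of metastatic c-Myc-high. The fit of only the groups compared does not exist for the last 2 comparisons.

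DESeq2 included 335 of the 335 site calls in c-Myc-high cells and 223 of 225 in c-Myc-low cells, and limma-voom 299 and 216. DESeq2 size factors moved the median log2 change of all genes by 0.169 for c-Myc status in primary cells, 0.111 in metastases and 0.146 over both sites.

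Replicate numbers were tried as a block although residuals of same-numbered libraries correlated by only 0.061 in primary and 0.107, -0.186 and -0.226 in metastatic cells, so the numbers were not taken to pair samples. Metastatic c-Myc-high replicates 1, 2 and 3 correlated best with c-Myc-low replicates 2, 3 and 1 (0.251, 0.512 and 0.303), a hint from the data and not from the labels, and such pairs were not fitted. Of these, c-Myc-high replicate 2 and c-Myc-low replicate 3 also shared low Xist, at 10.4 and 12.1 CPM. The main tests of c-Myc status in metastases treat all libraries as unpaired. With the replicate number as block 49 genes (3 higher and 46 lower) were called between sites in c-Myc-high and 39 (0 and 39) in c-Myc-low cells.

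Of 730 values for 43 called lists, 636 kept direction and call, 89 lost the call and 5 turned, by the direction of camera's test. The melanocyte median was 0.47 in the site comparison of c-Myc-high cells with the 8 deepest libraries. The mitosis median there ranged from -1.64 to 1.12 with 1 library left out, turning without primary c-Myc-high replicate 1. In metastases, without the libraries rich in salivary transcripts, the ER stress median was -0.33 and the keratinocyte median -0.36. The fibroblast interaction ranged from -5.42 to 1.78 with 1 library left out, turning without primary c-Myc-high replicate 2. The median alone changed sign, with the call lost, for oxidative phosphorylation in primary cells (-0.07) and for mitosis (-0.30) and keratinocyte genes (-0.25) over both sites, each without primary c-Myc-high replicate 1. It did so too for the fibroblast interaction in the 8 deepest libraries (1.53). The keratinocyte and pan-leukocyte calls between sites held in 17 of 17 alternatives in both c-Myc classes. These alternatives used the preset correlation between genes. With an estimated one the keratinocyte calls held and the pan-leukocyte calls did not. List tests were not run with DESeq2, limma-voom, RPKM, the block or only the groups compared.

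Of 3302 values for 146 named gene results, 2710 kept direction and call, 146 uncalled values changed sign, 113 passed newly and 333 lost the call. None that was called in either fit turned. A count of 3 stood for 3.57 CPM in primary c-Myc-high replicate 2, which had the lowest total, and for 2.04 CPM in metastatic c-Myc-high replicate 3.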

Other observations

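No test of an explanation is reported in this part, and the values of Xist and Y-linked genes, the keratin share and the ribosomal protein list were chosen only after the data had been seen.

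Further lists passed camera between metastatic and primary c-Myc-low cells. Of 14 chemokines and receptors of lymph node homing Cxcr4 rose and Ccl27a fell, and 6 rose and 1 fell when adjusted over the list alone, with a median of 4.89 (camera, adjusted p = 0.000133, and adjusted p = 0.226 with an estimated correlation). Interferon response genes had a median of 2.60 with 28 of 31 positive, 0 called and 2 higher when adjusted over the list alone (camera, adjusted p = 3.11e-06, and adjusted p = 0.226 with an estimated correlation). MHC class II genes had a median of 5.73 with 10 of 10 positive, 0 called and 6 higher when adjusted over the list alone (camera, adjusted p = 5.43e-06, and adjusted p = 0.481 with an estimated correlation). T cell genes had a median of 5.90, or 4.69 with members at 0 counts set to their bound, with 0 of 14 called and 7 higher when adjusted over the list alone (camera, adjusted p = 1.37e-07, and adjusted p = 0.481 with an estimated correlation). Endothelial genes had a median of 4.55, or 3.82 with bounds, with 0 of 12 called and 2 when adjusted over the list alone (camera, adjusted p = 2.41e-05, and adjusted p = 0.33 with an estimated correlation). The pan-leukocyte list was also higher in the metastatic cells, with a summed CPM of 506, 1780 and 4176 in metastatic c-Myc-low replicates 1, 2 and 3. It was 22.8 and 65.9 in primary c-Myc-low replicates 1 and 2. Whether the lists above followed this sum from library to library was not tested.

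Single genes of the plasma cell and vessel lists moved the other way. Sdc1, a syndecan of plasma cells and epithelia, fell, with log2 changes of -7.99 in c-Myc-high and -5.79 in c-Myc-low cells (adjusted p = 0.0117 and 0.0325). Notch3, a receptor of mural cells that epidermis also expresses, fell in c-Myc-high cells from 228 to 6.07 CPM (adjusted p = 0.0123).

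Keratin genes, 51 in all, took 4.59% and 2.39% of the count in primary c-Myc-high replicates 1 and 2 and 4.76% and 1.99% in primary c-Myc-low replicates 1 and 2. In the metastatic libraries their share lay between 0.00548% and 0.0378%. Melanocyte list genes summed to 6510 and 1296 CPM in primary c-Myc-high replicates 1 and 2, 2163 and 2490 CPM in primary c-Myc-low replicates 1 and 2, and between 4121 and 30090 CPM in the metastatic libraries.

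Xist, transcribed from the inactive X chromosome, had 6851 and 20.2 CPM in primary c-Myc-high replicates 1 and 2, where 4 Y-linked genes summed to 12.5 and 203 CPM. The primary c-Myc-low replicates 1 and 2 had 4536 and 4367 CPM of Xist. Xist was 2381, 10.4 and 2433 CPM in metastatic c-Myc-high replicates 1, 2 and 3 and 2243, 4874 and 12.1 CPM in metastatic c-Myc-low replicates 1, 2 and 3. The 4 Y-linked genes summed to 141 and 165 CPM in metastatic c-Myc-high replicate 2 and metastatic c-Myc-low replicate 3. Libraries that share a replicate number thus differed in these values in 3 cases. Replicates within primary c-Myc-high, metastatic c-Myc-high and metastatic c-Myc-low also differed, as libraries from animals of different sex would. Primary c-Myc-low had only high Xist, so the primary c-Myc classes were not balanced in this, and no covariate was fitted.

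Among 60 cytosolic ribosomal protein genes the median log2 change between c-Myc-high and c-Myc-low cells was 0.34 in primary and 0.48 in metastatic cells, beside 0.68 and 0.73 for oxidative phosphorylation genes. Levels of these ribosomal genes were uneven. Rpl4 had 292 to 1929 CPM over the libraries, but Rpl19 had 0.85 to 8.56 and Rps6 0 to 13.65 CPM. Their median is therefore a weak reference for ribosomal protein expression. Other lists past camera between c-Myc classes in metastases had medians of 0.46 (ribosome biogenesis, adjusted p = 0.00763), 0.45 (TCA cycle, adjusted p = 0.0195), 0.34 (mitosis, adjusted p = 0.0307), -0.69 (neural crest, adjusted p = 0.0346) and -0.66 (melanocyte, adjusted p = 0.0393), each with adjusted p = 0.998 with an estimated correlation. Each of these calls ended when metastatic c-Myc-high replicate 2 was left out, except that of the TCA cycle (adjusted p = 0.122, 0.119, 0.695 and 0.949). The mitosis call also ended without metastatic c-Myc-high replicate 3 or metastatic c-Myc-low replicate 2 or 3 (adjusted p = 0.25, 0.0772 and 0.0565). The neural crest call ended without primary c-Myc-high replicate 1 or 2, primary c-Myc-low replicate 2, metastatic c-Myc-high replicate 1 or metastatic c-Myc-low replicate 1 or 2 (adjusted p = 0.059, 0.0779, 0.0767, 0.26, 0.125 and 0.0857). The melanocyte call ended without primary c-Myc-low replicate 1 or 2, metastatic c-Myc-high replicate 1 or metastatic c-Myc-low replicate 1 (adjusted p = 0.0585, 0.0613, 0.215 and 0.725). The TCA cycle call ended without metastatic c-Myc-high replicate 1 or 3 or metastatic c-Myc-low replicate 2 or 3 (adjusted p = 0.108, 0.0679, 0.1 and 0.0584), in the 8 deepest libraries (adjusted p = 0.0594) and without the libraries rich in salivary transcripts, with a median of 0.18 (adjusted p = 0.335). The mitosis call also ended in these latter fits (adjusted p = 0.222 and 0.116) and with the strict filter (adjusted p = 0.0518). The neural crest call ended with no filter and with the strict one (adjusted p = 0.0884 and 0.113), and the melanocyte call with DESeq2 size factors and the strict filter (adjusted p = 0.059 and 0.0518).

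Remaining lists past camera are given here with their adjusted p, and with that from an estimated correlation after it. In c-Myc-high cells endothelial genes had a median of 5.49 between sites, or 3.42 with bounds (0.0329 and 0.839), a call that ended without primary c-Myc-high replicate 1 or 2 or metastatic c-Myc-high replicate 2 or 3 (adjusted p = 0.21, 0.127, 0.0603 and 0.274) and in the 8 deepest libraries (adjusted p = 0.303). In c-Myc-low cells the dendritic cell (0.00332 and 0.6), NK cell (0.00394 and 0.481) and neutrophil lists (0.0118 and 0.804) were higher between sites, the last not without metastatic c-Myc-low replicate 3 (adjusted p = 0.0556). Ribosome biogenesis had a median of -0.51 (0.0215 and 0.595), not called without primary c-Myc-low replicate 1 or metastatic c-Myc-low replicate 1 (adjusted p = 0.228 and 0.0653). Over both sites c-Myc status gave medians of 0.54 for mitosis (0.00806 and 0.906), 0.74 for keratinocyte genes (0.0201 and 0.906) and 0.54 for ER stress genes (0.0271 and 0.893). Without primary c-Myc-high replicate 1 none of these 3 was called, at -0.30, -0.25 and 0.28 (adjusted p = 0.913, 0.506 and 0.0573). Mitosis also lost its call without primary c-Myc-low replicate 1 (adjusted p = 0.0521). Keratinocyte genes lost it without primary c-Myc-low replicate 2 or metastatic c-Myc-high replicate 1 or 3 (adjusted p = 0.0766, 0.105 and 0.0522), and ER stress genes without primary c-Myc-high replicate 2 or those same 3 libraries (adjusted p = 0.108, 0.0766, 0.132 and 0.0522). Without the libraries rich in salivary transcripts the keratinocyte median was 0.13 and the ER stress median 0.19 (adjusted p = 0.43 and 0.418), and ER stress was also not called in the 8 deepest libraries (adjusted p = 0.197). By fry, which compares no list with other genes, 2 lists moved on balance in 1 direction between sites in c-Myc-high and 3 in c-Myc-low cells, and 0 in the other comparisons. By its test of change in either direction 15 lists passed between sites in c-Myc-high and 9 in c-Myc-low cells, and for c-Myc status 1 in primary cells, 0 in metastases, 4 over both sites and 0 for the interaction.

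The RPKM values imply between 18.83 and 29.53 times 1e6 reads per library, and the deposited counts sum to between 8.09% and 26.9% of these.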
